A study of Mus musculus with 6 samples.

How the data were processed

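RNA was extracted from mouse brain tissue with Trizol and made into strand-specific libraries with a TruSeq kit, per the labels' protocols. The 6 libraries were grouped by their titles into 3 control and 3 WNT3 overexpression samples, and each column of the deposited tables was matched to its sample through the library name in the labels. The tissue is given as auditory cortex in the sample labels and as striatum in the extraction protocol, and the data were analysed under the tissue label.

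The submitters' processing notes list FastQC 0.11.5, STAR 2.5.3a, Cuffnorm and DESeq 1.16.1, and the genome build mm10, without saying what each was used for. The deposited count table holds whole-number counts per gene, with no normalization, and 1 column per library. The program that made the counts, the gene annotation and the strand setting are not given in the sources used here. The deposited TPM table holds the authors' TPM values for the same genes in the same order, with each library scaled to the same total. Because the strand setting of the counting is unknown, a gene and its antisense partner may share reads. Near-identical copies, such as the haemoglobin genes, the Serpina3 family and Lilr4b with Lilrb4a, may also share reads. Of the 50559 gene names, 48908 were found in the RefSeq annotation of GRCm38.p6 and 37796 in GENCODE M21, both of the mm10 assembly. Coordinates are from GENCODE M21. List members missing by name were looked up through synonyms and gene identifiers in these tables.

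Total counts per library ranged from 42614588 to 71803617. Of the listed genes, 15448 had no count in any library. Genes were kept for testing by filterByExpr of edgeR (minimum count 10, by group), which left 22360 genes holding over 99.9% of the counts of each library. A gene with no count in a group was given a floor of 3 counts over that group, which is 0.0203 CPM in control and 0.0158 CPM in overexpression, and its fold is stated as a lower bound that covers counting error only.

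The comparison of overexpression with control used the edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest) in R 4.3.3 on the deposited counts, with TMM factors, group as the only term, 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the size of the fold change divided by the square root of the quasi-likelihood F. Expression is given as CPM over TMM-scaled library sizes, with the mean and SD of 3 libraries. A rank or permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so none was used to call genes or lists. Counts over the 10 splits of the libraries into 3 and 3 are given as a description only.

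Gene lists covering Wnt signalling, brain cell types and regions, synapses, neuronal activity, immune and glial responses, metabolism, stress and sex were fixed, 49 in all. Each was tested against all other tested genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 49 lists. The test was repeated with an estimated correlation, and with fry, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes. Fry for change in either direction was added after the data were seen. For each list the edgeR p-values were also adjusted over the list alone. In 5 lists, none of them called, the median and the direction of camera differed in sign.

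The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Wnt3, the genes with the largest changes among those that passed and, where fewer than 10 genes passed, the 10 with the smallest p. It also took, from a list in which no member passed, up to 2 members with the smallest p, and left unnamed gene models out. Since no gene passed, the parts on passing genes named none. Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) with and without a mean TPM minimum of 0.5, the replicate number as a block, the omission of each library, the omission of mitochondrial and haemoglobin genes, an adjusted p of 0.1 and a minimum fold. Robust empirical Bayes, voom with sample quality weights, removal of a trend on transcript length, and DESeq2 and the bounds on folds without each library were chosen after seeing the data. Transcript length was taken as the ratio of deposited counts to TPM, which gave a relative length for all 22360 genes, and the trend was a lowess fit (span 0.3) per library. In comparing settings, a list that passed the threshold in neither of the settings compared was taken to have no direction to lose.

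The tests were tried on simulated counts for the same 22360 genes, drawn from the means, library sizes and dispersions of these libraries, with 200 genes changed, all with a mean CPM of 1 or more, and each gene drawn independently of the others. In this simulation of overexpression against control, edgeR recovered 19.1%, 72.7% and 97.0% of genes changed by a log2 fold of 1, 2 and 3, with 3 false calls (2.34% of its calls). DESeq2 recovered 50.0%, 95.5% and 98.5%, with 54 false calls. A simulated list shifted by 0.6 on the log2 scale gave an adjusted p of 2.57e-10 by camera with the preset correlation, 0.0755 with an estimated correlation and 0.0065 by fry, and none of these called a list that had not been shifted. Fry for either direction gave a list with shifts of 0.6 up and down an adjusted p of 0.000231 and called 2 unshifted lists. Real genes of a list vary together, which these simulated lists did not include. No simulated library stood apart from the rest as control 2 did.

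Replicates were compared for duplication, and every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom from 21.0 to 311).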

Results

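Gene expression in the auditory cortex of C57 mice was measured by RNA sequencing in 6 libraries, 3 labelled control and 3 labelled WNT3 overexpression. The study asked which molecular changes follow overexpression of Wnt3, a secreted ligand of the Wnt family, in this part of the brain. The tissue label reads auditory cortex, whereas the extraction protocol speaks of striatum samples. The labels do not say how the gene was overexpressed, what the control mice received or whether replicates are separate animals, so p-values measure only the spread between these samples. Total counts were 42614588, 55859274 and 51119859 in control libraries 1 to 3 and 54642400, 61559379 and 71803617 in overexpression libraries 1 to 3. Of 50559 listed genes, 22360 had enough counts to be tested. Axin2, Lef1, Nkd1, Foxp2, Osmr, Steap4, Ccr2, Jchain, Fn1, Fos, Junb, Dusp1, Rn18s-rs5, Neat1, Acer2, Tgm2, Nrep, Epha8, Rspo1, Ddx3y, Csf3r, Igkc and Cd8a were chosen after their values were seen, and the other genes were named by a fixed rule.

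Wnt3 itself was higher in all 3 overexpression libraries than in any control. The gene lies on chromosome 11, positions 103774150 to 103817957 on the plus strand of mm10 (GENCODE M21 annotation). Its TMM-normalised expression, in CPM (counts scaled to library size), was 2.70, 1.91 and 1.74 in the controls, a mean of 2.12 ± 0.51 (SD, n = 3). It was 98.8, 7.45 and 8.71 in the overexpression libraries, a mean of 38.3 ± 52.4 (SD, n = 3). The log2 fold change was 4.18 ± 1.02 (SE). It was 1.93 without overexpression library 1, the library with the highest level. The adjusted p of Wnt3 was 0.82 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes, and its unadjusted p from the same test was 0.0033. DESeq2 gave Wnt3 a log2 fold change of 4.19 but no adjusted p, so Wnt3 is not among the genes that DESeq2 called.

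**Figure D1:**
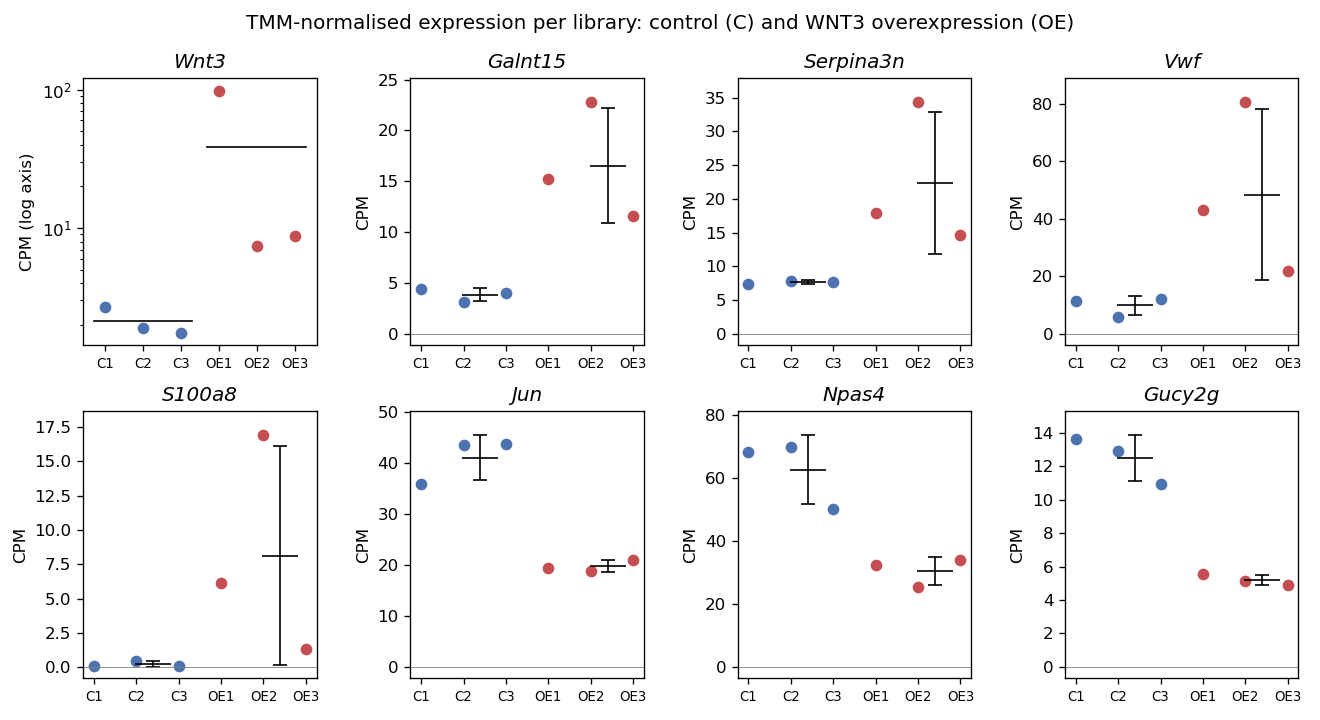
TMM-normalised expression of 8 genes in each library, in CPM on the vertical axes (a log axis for Wnt3, linear from 0 for the others). Blue points are control libraries (C1 to C3) and red points overexpression libraries (OE1 to OE3), black lines are group means, and error bars are the SD of 3 libraries (not drawn on the log axis). In each of the 8 genes the groups did not overlap, and Wnt3 reached 98.8 CPM in OE1 but 7.45 and 8.71 CPM in OE2 and OE3.

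Genes listed as targets or feedback regulators of canonical Wnt signalling had log2 fold changes in both directions. Of the 27 tested members of the list of Wnt/beta-catenin target and feedback genes, 17 were higher and 10 lower, with a median log2 fold change of 0.09 (-0.05 without overexpression library 1, with the test's direction up), and camera did not call the list (adjusted p = 0.88). Axin2, a general target and feedback inhibitor of the pathway, was at 21.9 ± 4.97 CPM in controls and 22.5 ± 2.28 CPM in overexpression (SD, n = 3), a log2 fold change of 0.04 ± 0.22 (SE). Lef1, a transcription factor of the pathway, had a log2 fold change of 0.51 ± 0.26 (SE), and Nkd1, a feedback inhibitor, one of -0.20 ± 0.24 (SE). The members with the smallest p were Jun, which was lower, and Cd44, which encodes a hyaluronan receptor and had a log2 fold change of 1.17 ± 0.44 (SE) with groups that overlapped. Jun is also in the immediate early list, and Cd44 in the reactive astrocyte and infiltrate lists, so neither gene speaks for the Wnt list alone. Jun alone passed when p-values were adjusted over the list alone; by edgeR no member passed over all genes, 5 had an unadjusted p under 0.05 (2 higher, 3 lower), and DESeq2 called 1. Fry for change in either direction, a test added after the data were seen, gave this list an adjusted p of 0.00652 and called 1 of the 49 lists with all libraries, but 0 without controls 1 or 3 or overexpression libraries 1 or 2 (adjusted p of this list 0.151, 0.0545, 0.47 and 0.297). With the replicate number as a block, fry for either direction also called 0 (adjusted p of this list 0.342). It called 3 lists with no filter on low counts, 4 without control 2, 4 without overexpression library 3 and 7 with the length trend removed (adjusted p of this list 0.00715, 0.00596, 0.0411 and 0.00024); the list had an adjusted p of 0.198 without Jun, and in simulated counts the same test called 2 unshifted lists.

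Other parts of the Wnt system showed few differences. The receptor gene Fzd10 was lower, at 2.13 ± 0.07 CPM in controls and 0.63 ± 0.19 CPM in overexpression (SD, n = 3), and was the 1 member of 32 receptors and cytoplasmic transducers to pass when adjusted over the list alone. The vascular Wnt receptor Fzd4 had a log2 fold change of 0.65 ± 0.29 (SE) with groups that overlapped. Among 13 other Wnt ligands, 8 were lower, with log2 fold changes of -0.65 ± 0.25 (SE) for Wnt9a and -0.66 ± 0.30 (SE) for Wnt7a. Camera called neither the receptors (adjusted p = 0.86), nor the other ligands (adjusted p = 0.34), nor the planar cell polarity and calcium arm (adjusted p = 0.28). The 15 tested neighbours of Wnt3 on chromosome 11 had a median log2 fold change of 0.01, or -0.06 to 0.07 without single libraries (camera adjusted p = 0.81). Of 28 genes linked to speech, reading and vocalisation, 19 were higher, with a median log2 fold change of 0.17 (camera adjusted p = 0.12). That median was -0.05 without control 2 (adjusted p = 0.892), 0.07 without overexpression library 1 and 0.02 with the length trend removed, 0.26 without control 1 and 0.27 without control 3, where camera called the list (adjusted p = 0.0449). Foxp2 stood at 18.9 ± 3.35 CPM in controls and 18.3 ± 4.95 CPM in overexpression (SD, n = 3).

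Across the transcriptome, no gene passed an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.822. An unadjusted p under 0.05 was reached by 1040 genes (415 higher and 625 lower in overexpression), against 1118 that chance alone would give. The limma voom test also called 0 genes (1032 at an unadjusted p under 0.05), whereas DESeq2 called 64, of which 36 were higher and 28 lower. With single libraries left out, DESeq2 called from 13 genes (without overexpression library 2) to 132 (without control 2), which held 7 and 46 of the 64. Of those 64 genes, edgeR tested 60, all with an unadjusted p under 0.05, and 59 of the 60 had groups that did not overlap. DESeq2 selected them on the same counts, so this is no independent support. Their lowest adjusted p in edgeR was 0.822. Groups did not overlap in 2667 of the tested genes (11.9%, where chance gives 10%). In simulated counts with the spread of these libraries, DESeq2 made 54 false calls, 25% of its calls, and edgeR 3.

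The 10 named genes with the smallest edgeR p all had an adjusted p of 0.822 and groups that did not overlap. Galnt15, which encodes an enzyme that starts O-linked glycosylation, was at 3.85 ± 0.64 CPM in controls and 16.5 ± 5.70 CPM in overexpression (SD, n = 3), a log2 fold change of 2.10 ± 0.30 (SE). Il1r1, the receptor for interleukin-1, was at 4.40 ± 1.34 and 14.8 ± 3.79 CPM (SD, n = 3). Mmp8, a collagenase stored by neutrophils, had no count in any control and 1.07, 2.63 and 0.50 CPM in the overexpression libraries, at least 67.5-fold higher, a bound that ran from 37.1 without overexpression library 2 to 93.2 without overexpression library 3. Lilr4b, a leukocyte receptor gene, and the antisense transcript Cd55os also had no control count and were at least 32.7-fold and 24.4-fold higher. The 3 bounds were 42.6, 20.6 and 15.4 without control 2 and 44.4, 21.5 and 16.04 without control 3, as fewer control reads set the floor. Lilrb4a and the protease inhibitor Serpina3g had log2 fold changes of 2.67 ± 0.50 and 3.01 ± 0.53 (SE), from control means of 0.31 and 0.15 CPM. Lower in overexpression were Jun (-1.06 ± 0.17, log2 ± SE), the guanylate cyclase Gucy2g (-1.26 ± 0.21) and the postsynaptic gene Prr7 (-2.01 ± 0.37). Lilr4b and Lilrb4a are close paralogs, the Serpina3 genes form a family of near copies, and Cd55os overlaps genes on the other strand, so counts of these may hold reads of their relatives.

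The list of reactive astrocyte genes had a higher median in every overexpression library than in any control. It shares members with the interferon-stimulated, antigen presentation, complement, cytokine, infiltrate, immediate early and glucocorticoid-responsive lists. It also shares members with the Wnt target, astrocyte marker and heat shock lists, so these results are not independent. Of 31 tested members, 28 were higher, with a median log2 fold change of 0.64. By library, the list's median log2 difference from the control mean was 0.85, 0.46 and 0.33 in overexpression libraries 1 to 3, against -0.26, 0.05 and 0.16 in the controls. Lcn2, an iron-binding acute-phase protein, was at 0.17 ± 0.20 CPM in controls and at 7.47, 37.1 and 1.88 CPM in the overexpression libraries. Serpina3n, a secreted protease inhibitor, was at 7.61 ± 0.28 and 22.3 ± 10.5 CPM (SD, n = 3), and Osmr, the oncostatin M receptor, at 4.40 ± 1.93 and 16.5 ± 6.84 CPM (SD, n = 3). Camera called the list (adjusted p = 2.53e-08), with adjusted p = 0.733 with an estimated correlation; the median was 0.40 without overexpression library 1. By edgeR 0 members passed over all genes, 10 had an unadjusted p under 0.05, 4 passed when adjusted over the list alone (Lcn2, Serpina3n, Osmr and Steap4), and DESeq2 called 3. General astrocyte markers had a median log2 fold change of 0.03 over 21 members, or -0.03 to 0.12 without single libraries (camera adjusted p = 0.88), and Gfap, the intermediate filament of astrocytes, was at 114 ± 32.7 and 191 ± 65.2 CPM (SD, n = 3) with groups that overlapped.

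Markers of infiltrating leukocytes were also higher, at low levels. Of 30 T cell, B cell and myeloid infiltrate markers, 13 had enough counts to be tested and 11 of these were higher. The median log2 fold change was 0.77, or 0.45 without overexpression library 1 and 1.55 with no filter on low counts. By library, the median difference from the control mean was -0.43, 0.20 and 0.27 in the controls and 1.79, 0.45 and 0.85 in overexpression. S100a8 and S100a9, the subunits of calprotectin in neutrophils, had log2 fold changes of 4.94 ± 0.98 and 4.60 ± 1.17 (SE), from control means of 0.26 and 0.39 CPM to 6.17, 16.9 and 1.37 CPM and 8.29, 18.2 and 2.86 CPM in the overexpression libraries. Ccr2, a chemokine receptor of monocytes, was at 0.19 ± 0.12 CPM in controls (SD, n = 3) and at 2.55, 0.96 and 0.42 CPM in the overexpression libraries. Camera called the list (adjusted p = 0.000315), with adjusted p = 0.733 with an estimated correlation. By edgeR 0 members passed over all genes, 5 had an unadjusted p under 0.05, 4 passed when adjusted over the list alone (S100a8, S100a9, Ccr2 and Jchain), and DESeq2 called 1. Of 22 markers of resident microglia and macrophages, 16 were lower, with a median log2 fold change of -0.23 (camera adjusted p = 0.13). The median was 0.0069 without control 2 (adjusted p = 0.978, with the test's direction down), -0.09 without overexpression library 2 (adjusted p = 0.93, with the test's direction up) and -0.06 with the length trend removed, whereas camera called the list lower without control 1 (median -0.34, adjusted p = 0.0327) and without overexpression library 1 (median -0.45, adjusted p = 0.00066).

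Endothelial and extracellular matrix genes were higher as well. Of 27 endothelial and blood-brain barrier genes, 22 were higher, with a median log2 fold change of 0.30, or 0.18 without overexpression library 2. By library, the median difference from the control mean was 0.05, 0.04 and -0.06 in the controls and 0.21, 0.35 and 0.22 in overexpression. Vwf, the von Willebrand factor of endothelial cells, was at 9.84 ± 3.41 CPM in controls and 48.4 ± 29.8 CPM in overexpression (SD, n = 3), and the vascular receptor Flt1 at 54.0 ± 6.12 and 97.7 ± 21.6 CPM (SD, n = 3). Camera called the endothelial list (adjusted p = 0.000205), with adjusted p = 0.733 with an estimated correlation. Of 26 meningeal fibroblast and extracellular matrix genes, 24 were higher (median 0.61, camera adjusted p = 3.05e-05, adjusted p = 0.733 with an estimated correlation), and the median was 0.28 without overexpression library 1. By library, this list's median difference from the control mean was -0.04, -0.40 and 0.34 in the controls and 0.92, 0.71 and -0.15 in overexpression, so that overexpression library 3 lay below 2 controls. Choroid plexus markers stood at -0.01, -0.14 and 0.64 in the controls and 1.27, 0.37 and -0.07 in overexpression. The collagen genes Col6a1 and Col6a2 had log2 fold changes of 0.86 ± 0.18 (SE) each. By edgeR 0 members of either list passed over all genes; when adjusted over the list alone, 2 endothelial (Vwf and Flt1) and 3 matrix genes (Col6a1, Col6a2 and Fn1) passed. An unadjusted p under 0.05 was reached by 6 and 6 members, and DESeq2 called 1 and 2. Pericyte and smooth muscle markers had a median of 0.04, or -0.10 to 0.05 without single libraries (camera adjusted p = 0.87).

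Immediate early genes, which neurons switch on with activity, were mostly lower, but their medians by library overlapped between the groups. Of 35 members, 28 were lower, with a median log2 fold change of -0.51. Jun lay below every control in each overexpression library, at 19.4, 18.8 and 21.0 CPM against 35.9, 43.5 and 43.8 CPM in the controls. Npas4, an activity-dependent transcription factor, was at 62.7 ± 10.9 CPM in controls and 30.4 ± 4.51 CPM in overexpression (SD, n = 3). Fos was at 56.0 ± 21.3 and 20.3 ± 4.06 CPM, and Junb at 47.3 ± 23.4 and 15.0 ± 1.51 CPM (SD, n = 3). Camera called the list (adjusted p = 7.29e-06), with adjusted p = 0.733 with an estimated correlation. By edgeR 0 members passed over all genes, 11 had an unadjusted p under 0.05, 5 passed when adjusted over the list alone (Jun, Npas4, Junb, Fos and Dusp1), and DESeq2 called 4. By library, the list's median difference from the control mean was -0.59, 0.25 and 0.25 in controls 1 to 3 and -0.72, -0.76 and -0.08 in overexpression libraries 1 to 3, so that overexpression library 3 lay above control 1. Striatal projection neuron markers stood at -0.50, -0.02 and 0.54 in the same controls and -0.29, -0.59 and 0.03 in the same overexpression libraries. The immediate early median was -0.33 without control 3 and -0.78 without overexpression library 3.

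**Figure D2:**
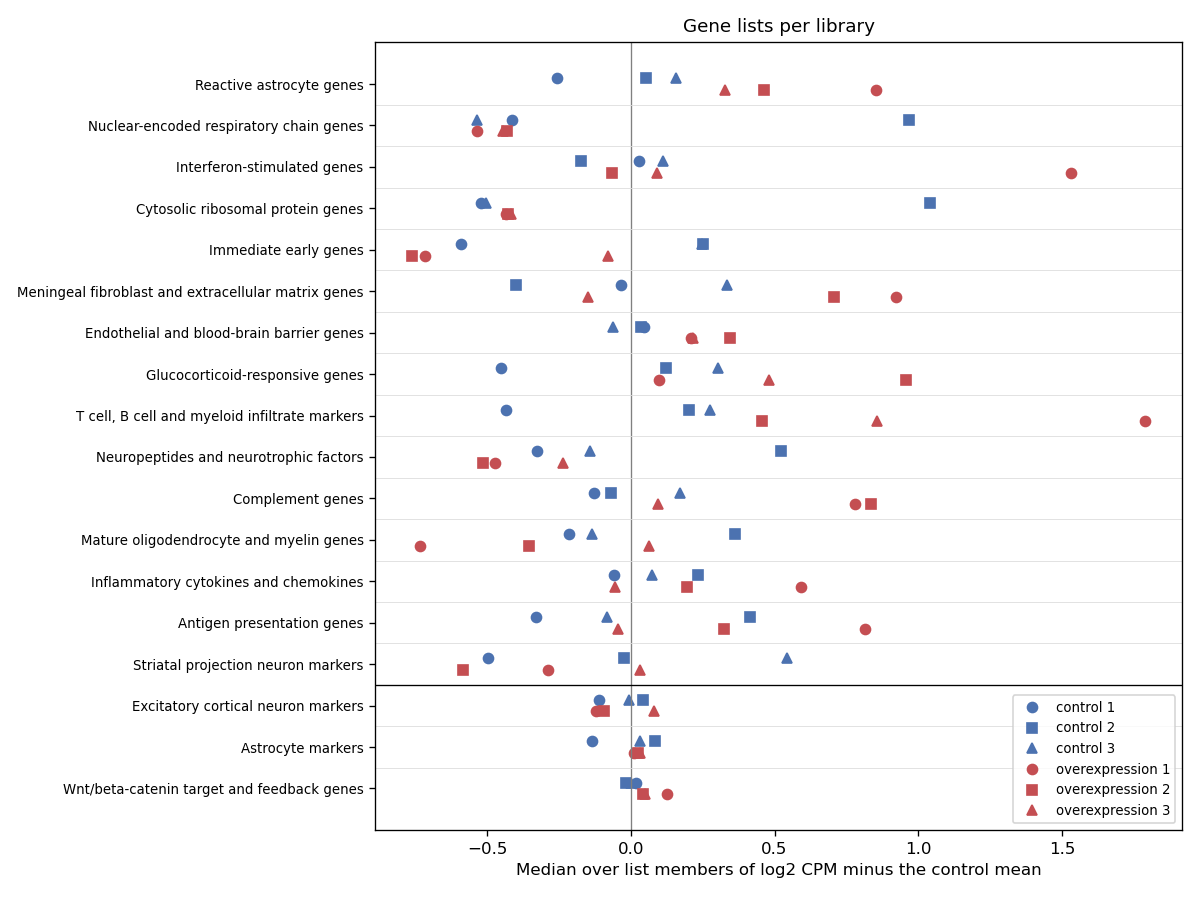
Median over the members of each gene list of log2 CPM minus the control mean (horizontal axis), for the 15 lists called by camera above the line and 3 others below it. Blue symbols are control and red symbols overexpression libraries. Reactive astrocyte genes lay at 0.33 to 0.85 in the overexpression libraries, interferon-stimulated genes at 1.53 in overexpression library 1 alone, and ribosomal protein genes at 1.04 in control 2 alone.

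Interferon-stimulated genes were high in overexpression library 1. All 38 tested members had a fitted log2 fold change above 0 (median 0.62), but the list's median difference from the control mean was 1.53, -0.07 and 0.09 in overexpression libraries 1 to 3. Oas2, an antiviral enzyme, was at 1.01 ± 0.29 CPM in controls and at 4.69, 1.54 and 1.48 CPM in the overexpression libraries, and Cxcl9, a chemokine, at 0.93, 0.61 and 0.27 CPM against 0.03 ± 0.05 CPM in controls. Camera called the list (adjusted p = 4.48e-06), with adjusted p = 0.733 with an estimated correlation. Without overexpression library 1 the median was 0.039 and camera no longer called the list (adjusted p = 0.79). By edgeR 0 members passed over all genes or when adjusted over the list alone, and 5 had an unadjusted p under 0.05; DESeq2 called 0.

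Camera also called further immune lists and a list of hormone-responsive genes higher, but their medians by library overlapped between the groups. Complement genes had a median log2 fold change of 0.58 (14 of 17 higher, camera adjusted p = 0.0016), with C4b at 16.4 ± 8.51 CPM in controls and 51.7 ± 26.8 CPM in overexpression (SD, n = 3). Inflammatory cytokines and chemokines had a median of 0.40 (13 of 19 higher, camera adjusted p = 0.0099), with Cxcl12 at 36.1 ± 5.28 and 56.2 ± 8.81 CPM (SD, n = 3). Antigen presentation genes had a median of 0.36 (18 of 23 higher, camera adjusted p = 0.022), with Nlrc5, a regulator of MHC class I, at a log2 fold change of 1.71 ± 0.47 (SE). Glucocorticoid-responsive genes had a median of 0.58 (16 of 19 higher, camera adjusted p = 0.000217), with Plin4, a lipid droplet protein, at 3.45, 3.67 and 9.65 CPM in the controls and at 8.77, 104 and 25.01 CPM in overexpression, so that its groups overlapped. By library, the complement median difference from the control mean was -0.13, -0.07 and 0.17 in the controls and 0.78, 0.84 and 0.09 in overexpression. The cytokine median stood at -0.06, 0.23 and 0.07 in the controls and 0.59, 0.19 and -0.06 in overexpression, and the antigen presentation median at -0.33, 0.42 and -0.08 and at 0.81, 0.33 and -0.04. The glucocorticoid-responsive median stood at -0.45, 0.12 and 0.30 in the controls and 0.10, 0.96 and 0.48 in overexpression. The adjusted p with an estimated correlation was 0.738 for antigen presentation and 0.733 for the other 3 lists. The glucocorticoid-responsive median was 0.22 without overexpression library 2. Without control 1 camera no longer called any of these 4 lists, at medians of 0.64, 0.29, 0.19 and 0.37 for complement, cytokine, antigen presentation and glucocorticoid-responsive genes (adjusted p = 0.071, 0.097, 0.345 and 0.071). Without overexpression library 1 the complement median was 0.36, and the cytokine and antigen presentation calls were lost at medians of 0.34 and 0.11 (adjusted p = 0.108 and 0.49), as they were without control 3 at medians of 0.41 and 0.28 (adjusted p = 0.0523 and 0.254). The cytokine call was also lost with a filter of 1 CPM in 3 libraries (median 0.046, adjusted p = 0.207), and the antigen presentation median was 0.66 without control 2 and 0.60 with the length trend removed.

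Camera called neuropeptide and myelin genes lower, and their medians by library overlapped between the groups. The neuropeptide median difference from the control mean was -0.33, 0.52 and -0.14 in controls 1 to 3 and -0.47, -0.52 and -0.24 in overexpression libraries 1 to 3, and the myelin median -0.22, 0.36 and -0.14 and -0.73, -0.36 and 0.06. Of 29 neuropeptides and neurotrophic factors, 20 were lower (median -0.47, camera adjusted p = 0.000908, adjusted p = 0.733 with an estimated correlation). Adcyap1, the precursor of the neuropeptide PACAP, was at 17.6 ± 2.75 CPM in controls and 10.1 ± 1.39 CPM in overexpression (SD, n = 3), and the satiety peptide gene Cartpt had a log2 fold change of -1.75 ± 0.47 (SE), from 4.90, 12.8 and 3.72 CPM in the controls to 1.77 to 2.38 CPM in overexpression. Without control 2 the median was -0.10 and the call was lost (adjusted p = 0.184), and with the length trend removed it was -0.29. Of 24 mature oligodendrocyte and myelin genes, 19 were lower (median -0.28, camera adjusted p = 0.0045, adjusted p = 0.733 with an estimated correlation), with Opalin, an oligodendrocyte membrane protein, at a log2 fold change of -1.28 ± 0.29 (SE). That call was lost without overexpression library 1 (median -0.17, adjusted p = 0.689), and the median was -0.11 without control 2 and -0.46 without overexpression library 3.

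Ribosomal and respiratory chain genes were highest in 1 control library. All 50 cytosolic ribosomal protein genes had a log2 fold change below 0 (median -0.63, camera adjusted p = 6.63e-06) and so did 45 of 46 nuclear-encoded respiratory chain genes (median -0.67, camera adjusted p = 9.04e-07); for both lists adjusted p = 0.733 with an estimated correlation. Relative to the control mean, the ribosomal median was 1.04 in control 2 and between -0.52 and -0.42 in the other 5 libraries, and the respiratory chain median 0.97 in control 2 and between -0.54 and -0.42 in the others. Without control 2 the ribosomal median turned to 0.083 (camera adjusted p = 0.0035) and the respiratory chain median was 0.0037 (camera adjusted p = 0.588, with the test's direction down). With a trend on transcript length removed, the medians were -0.13 and -0.18. Rpl13, a protein of the large ribosomal subunit, was at 115, 321 and 74.9 CPM in controls 1 to 3 and at 73.6 to 83.3 CPM in overexpression.

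Control 2 differed from all other libraries in general. Its log2 CPM correlated with theirs across genes at r = 0.933 to 0.946, against 0.971 to 0.979 among the other 5, and it alone defined the first principal component (46.8% of the variance). The ribosomal RNA gene Rn18s-rs5 took 1.39% of its counts, against 0.293% to 0.448% elsewhere, and mitochondrial ribosomal RNA 2.57%, against 1.27% to 1.54%. In control 2 the quintile of genes with the shortest transcripts had a median deviation of 0.86 from the mean of the other libraries on the log2 scale, and the quintile with the longest one of -0.65. Without control 2, edgeR still called 0 genes (1309 at an unadjusted p under 0.05, DESeq2 132), and camera called 23 lists.

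**Figure D3:**
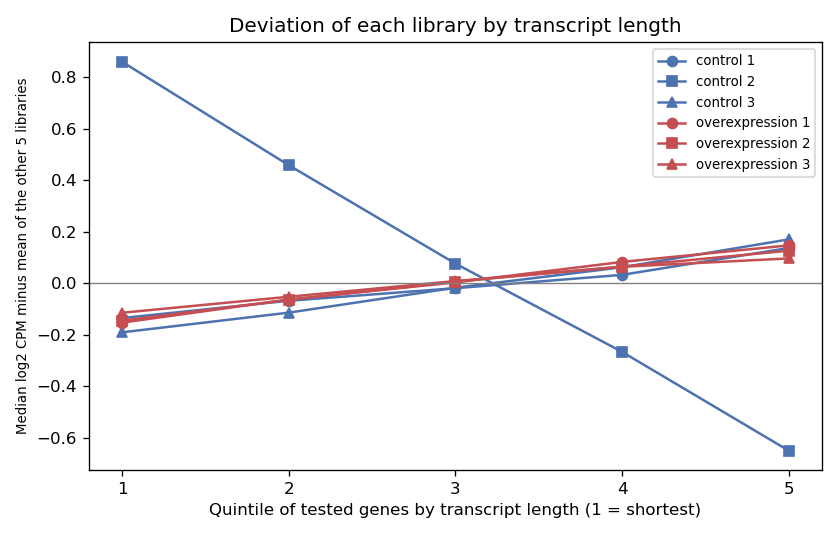
Median deviation of each library from the mean of the other 5, in log2 CPM, over quintiles of the 22360 tested genes ordered by transcript length (1, shortest; 5, longest). Control 2 ran from 0.86 in the shortest quintile to -0.65 in the longest, and the other 5 libraries stayed between -0.19 and 0.17.

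Markers of excitatory and inhibitory cortical neurons had medians near 0, and camera called striatal projection neuron markers lower, although their medians by library overlapped between the groups. Excitatory cortical neuron markers had a median log2 fold change of -0.05 over 25 members (camera adjusted p = 0.34) and GABAergic interneuron markers one of -0.05 over 25 (camera adjusted p = 0.37). The excitatory median was -0.11 without overexpression library 3, -0.0053 without overexpression library 1 and -0.14 with the length trend removed, where camera called the list (adjusted p = 0.0153). The interneuron median was -0.23 without overexpression library 1 and 0.03 without control 2, with the test's direction down in both. Lamp5, a marker of upper-layer and neurogliaform neurons, was lower, at 234 ± 50.9 CPM in controls and 123 ± 3.57 CPM in overexpression (SD, n = 3), and passed when adjusted over the excitatory list alone. Striatal projection neuron markers had a median of -0.16 (18 of 21 lower, camera adjusted p = 0.032, adjusted p = 0.733 with an estimated correlation), a call that was lost without control 3 (median 0.02, with the test's direction down), overexpression library 1 (-0.35) or overexpression library 2 (-0.23). The striatal mean over members was -0.45, and the median was -0.45 without control 1, -0.32 without control 2, -0.41 without overexpression library 3 and -0.27 with the length trend removed, where camera called the list. The striatal enkephalin gene Penk had a log2 fold change of -1.50 ± 0.46 (SE) with groups that overlapped. Hippocampal and thalamic markers had medians of -0.26 and -0.01 (camera adjusted p = 0.20 and 0.83), with 14 of 16 hippocampal markers lower. The hippocampal median was -0.06 without control 3 (adjusted p = 0.897), -0.14 with a filter of 1 CPM in 3 libraries, -0.44 without overexpression library 1 (adjusted p = 0.108) and -0.35 without control 2, where camera called the list (adjusted p = 0.0258). Synaptic vesicle, glutamate receptor, GABA receptor and voltage-gated channel genes had medians between 0.03 and 0.08, and camera called none of them (adjusted p = 0.437 to 0.859). Without control 2 it called 3 of these 4 lists lower, glutamate receptors at a median of -0.13 (adjusted p = 0.0004), GABA receptors at -0.12 (adjusted p = 0.0035) and voltage-gated channels at -0.10 (adjusted p = 0.00264). Without control 1 the medians of these 3 lists were 0.12, 0.12 and 0.17 (adjusted p = 0.855, 0.344 and 0.0626), and with the length trend removed they were -0.10, -0.06 and -0.08 (adjusted p = 0.00263, 0.0928 and 0.118).

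In all, camera with a preset inter-gene correlation of 0.01 called 15 of the 49 gene lists, 9 higher and 6 lower. Its direction went against the sign of the median in 5 lists that were not called, up for thalamic and erythrocyte genes and down for astrocyte markers, glutamate receptors and the neighbours of Wnt3. With an estimated correlation it called 0 (2 lists at an unadjusted p under 0.05), and fry called 0 (2 lists at an unadjusted p under 0.05). In both tests these were the endothelial and reactive astrocyte lists. The adjusted p of 0.733 is shared by lists with an unadjusted camera p from 0.030 (endothelial) to 0.434 (ribosomal), so it does not rank them. Camera with an estimated correlation also missed a simulated list shifted by 0.6 (adjusted p = 0.0755), so its 0 calls do not show that no list moved. The other 9 ways of dividing the 6 libraries into 3 and 3 gave up to 24 called lists. Several lists share members, so the calls are not independent of each other.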

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

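Robust empirical Bayes, voom with sample quality weights, removal of the length trend, fry for either direction, and DESeq2 and the bounds on folds without each library, were tests chosen only after the results were seen. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes under every scaling, filter, omitted library and threshold tried, and limma voom and limma-trend on TPM also called 0 (1040 genes at an unadjusted p under 0.05 in edgeR and 1032 in voom with all libraries). DESeq2 called 64 genes (36 higher, 28 lower). It called 88, 132 and 108 without controls 1 to 3 and 29, 13 and 64 without overexpression libraries 1 to 3, and shared 42, 46, 43, 18, 7 and 32 of those calls with the full set. Voom with sample quality weights, which gave control 2 a weight of 0.126 against 1.24 to 1.76 for the others, called 2 unnamed gene models (1 higher, 1 lower). The cause of these differences between tools was not tested. Lowest adjusted p-values in edgeR were 0.822 with all libraries, 0.322 without control 2 and 0.354 with the length trend removed.

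The Wnt3 log2 fold change stayed above 0 under all alternatives, from 1.93 without overexpression replicate 1 to 4.66 without overexpression replicate 2. With the deposited TPM values the median log2 fold change of all genes was 0.18, 0.23 and 0.14 (filtered with a pseudocount of 1, with 0.1, and unfiltered), against -0.0069 in edgeR, and no count-based setting moved it by over 0.1.

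Camera called 15 lists, 0 with an estimated inter-gene correlation and 0 by fry, while fry for either direction called 1, the Wnt target list. The latter test called between 0 and 4 lists without single libraries, 3 with no filter on low counts, 7 with the length trend removed, and 0 with a replicate block (adjusted p of the Wnt target list 0.342). Leaving out each library gave between 11 (without overexpression replicate 1) and 23 (without control replicate 2), the latter with 13 of the 15. The cytosolic ribosomal protein list ran from -0.89 without control replicate 1 to 0.083 without control replicate 2, where its direction reversed; the cause was not tested beyond the length trend of control 2. Other scalings called the same 15 lists, the filter of 1 CPM in 3 libraries called 15 with 14 of them, and the length trend removal called 20, the 15 among them. With that trend removed the ribosomal, respiratory chain and neuropeptide medians were -0.13, -0.18 and -0.29, against -0.63, -0.67 and -0.47 before.

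The labels do not say whether the shared replicate numbers pair the samples. Deviations from the group means correlated at 0.06, -0.02 and -0.01 between same-numbered libraries, and at -0.15 to 0.12 between differently numbered ones. With 3 libraries per group and control 2 standing apart, these values can neither show nor exclude pairing. With a replicate block, edgeR called 0 genes (751 at an unadjusted p under 0.05, lowest adjusted p 0.873) and camera the same 15 lists. Among lists not called, the block moved among others the medians of hippocampal (-0.13), cell division (-0.02), Notch, Hedgehog and BMP response (-0.08), ependymal (0.06) and erythrocyte genes (0.07).

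Depth limits the low genes: with no count in 3 libraries a level of up to 0.0203 CPM in controls cannot be excluded, and most of the neutrophil genes were under 1 CPM in controls. The ribosomal list was the only result past its threshold in both settings compared that reversed.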

Other observations

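The tests of transcript length, blood, meningeal tissue, overexpression library 1 and lymphocytes, and the counts of splits for edgeR and for fry in either direction, were chosen only after the results were seen.

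Genes called by DESeq2 alone held further named genes in both directions, which were chosen after their values were seen. Neat1, a nuclear long non-coding RNA, was at 137 ± 24.6 CPM in controls (SD, n = 3), with a log2 fold change of 0.98 ± 0.18 (SE). The ceramidase gene Acer2 was at 7.58 ± 2.26 CPM in controls and at 18.9, 52.0 and 22.5 CPM in the overexpression libraries, and the transglutaminase gene Tgm2 at 7.41 ± 1.32 and 20.9 ± 7.06 CPM (SD, n = 3). Lower in overexpression were Nrep (97.0 ± 10.3 and 53.5 ± 5.53 CPM), the ephrin receptor gene Epha8 (6.61 ± 0.37 and 2.93 ± 0.22 CPM) and Rspo1, a secreted enhancer of Wnt signalling (14.2 ± 5.30 and 5.60 ± 1.27 CPM; SD, n = 3). Each of these 6 genes had groups that did not overlap and an edgeR adjusted p of 0.822.

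The remaining lists, none called by camera with all libraries, had these medians. Activated microglia genes stood at 0.19, oligodendrocyte precursor markers at -0.13, choroid plexus markers at 0.48 and ependymal genes at -0.22. Cell division genes had a median of -0.15, immature neuron genes one of -0.07, and Notch, Hedgehog and BMP response genes one of -0.19. Axon guidance genes had a median of 0.14 (27 of 36 higher) and circadian clock genes one of 0.13, while the clock output gene Dbp was at 52.5 ± 23.9 CPM in controls and 24.9 ± 3.38 CPM in overexpression (SD, n = 3). Mitochondrially encoded genes had a median of -0.22, heat shock genes -0.19, cholesterol synthesis genes -0.13, endoplasmic reticulum stress genes -0.06, p53 and apoptosis genes 0.08, hypoxia and glycolysis genes 0.01 and erythrocyte genes -0.11. Single libraries moved these medians both ways, and camera called some of the lists without them. The activated microglia median ran from -0.03 without overexpression library 1 to 0.36 without control 2, and the list was called without control 2, without overexpression library 2 (0.34) and with the length trend removed (0.21). Precursor markers ran from -0.37 without overexpression library 3 to -0.08 without control 1 and were called without control 2 (-0.18) and with the length trend removed (-0.26). Choroid plexus markers ran from 0.05 without overexpression library 1 to 0.75 without overexpression library 3, ependymal genes from -0.68 without control 1 to 0.27 without control 2, and axon guidance genes from -0.06 without control 2 to 0.25 without control 3; the calls were at 0.75, -0.68 and 0.25. Hypoxia and glycolysis genes ran from -0.05 without overexpression library 3 and erythrocyte genes from -0.41 without control 1, to 0.11 and 0.72 without control 2, where both were called. Immature neuron genes ran from -0.23 without overexpression library 1 to 0.0055 without control 2 and were called without control 1 (-0.15). Heat shock genes ran from -0.29 without overexpression library 3 to -0.09 without overexpression library 2 and were called in the former and without control 1 (-0.25). Cholesterol synthesis genes ran from -0.27 to -0.03 without the same 2 libraries and were called in the former, without control 2 (-0.10) and with the length trend removed (-0.16). Mitochondrially encoded genes were called at -0.26 without overexpression library 3, -0.14 without control 2 and -0.23 with a filter of 1 CPM in 3 libraries, but stood at 0.01 with the length trend removed. Lists that no omitted library brought to a call ran from -0.22 to -0.07 (cell division), -0.30 to 0.02 (Notch, Hedgehog and BMP response), 0.01 to 0.18 (circadian clock), -0.21 to 0.04 (endoplasmic reticulum stress) and -0.06 to 0.12 (p53 and apoptosis). The test's direction went against the sign of the median for activated microglia, p53 and hypoxia genes (up) at their lowest medians, for immature neuron and Notch, Hedgehog and BMP response genes (down) at their highest, and for mitochondrially encoded genes (down) with the length trend removed. Sex-linked genes had a median of 0.20, which was 0.00066 without control 2 and was called at 0.35 and 0.30 without controls 1 and 3, and all 6 libraries expressed the Y-linked gene Ddx3y, chosen after its values were seen, at 64.2 to 103 CPM with Xist at 0.275 to 0.874 CPM.

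Control 2 differed from the other 5 libraries. A candidate explanation is a bias on transcript length, as partial RNA degradation or a different fragment selection could give: its median deviation was 1.51 higher (log2) in the shortest than in the longest quintile of genes, against at most 0.361 in size in the other libraries. The fitted trend did not account for all of it, as after its removal the mean correlation of control 2 with the others was 0.950 (0.939 before). That was still under the lowest pair among the others, 0.970. Effects of the same bias that a trend on length alone would not remove were not tested. A different mix of cell types or regions in control 2 stays open. After removal of the trend the most deviating marker list of control 2, meningeal fibroblast genes, stood at -0.62. However, the same list stood at 0.87 in overexpression library 1 and choroid plexus markers there at 1.28. The labels name no biological difference between control 2 and the other controls, so none from the design was tested.

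Reactive astrocyte genes were higher in overexpression, and 8 of 16 neutrophil genes, a list made after the data were seen and not tested for enrichment, were above all controls in each overexpression library, which may reflect Wnt3, the procedure used to deliver it, or injury at the site. More blood of the same make-up is argued against for the tested neutrophil genes only: their median log2 fold change (4.39 over 10 tested genes) exceeded the log2 ratio of haemoglobin (0.19 ± 0.86, SE) by at least 3.50 with all libraries, without each library and with the length trend removed, though erythrocyte genes were higher without control 2 and blood richer in neutrophils stays open. Some of the 10, such as Mmp8 with no control count, passed the filter on counts only through overexpression, which can raise that median. The 2 genes with a control mean of 1 CPM or more had groups that overlapped. The length bias of control 2 is argued against too, as the reactive astrocyte median stayed at 0.65 or more without control 2 or the length trend. Meningeal tissue carried along cannot be told apart: 0 libraries had the reactive list at least 0.3 above every control without the meningeal list above them too, although in overexpression library 3 the reactive list was 0.17 above every control and the meningeal list -0.48 relative to the highest control. Of the 16 neutrophil genes, 5 are in a fixed list, 2 had a control mean of 1 CPM or more, and the highest overexpression means were 15.5 CPM for Lcn2, also made by reactive astrocytes, 9.77 for S100a9, 8.22 for Csf3r, chosen after its values were seen and with groups that overlapped, and 8.15 for S100a8.

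The interferon-stimulated list was high in overexpression library 1 alone, which also had the most Wnt3. Its median without that library was 0.039. Lymphocytes in that library are a candidate source: 9 of 9 T and B cell genes, all in the fixed infiltrate list and none at 1 CPM in controls, had their highest CPM there, with Jchain at 25.7, Igkc at 11.1 and Cd8a at 1.77 CPM, 3 genes chosen after their values were seen. A link with the Wnt3 level rests on 1 library and was not tested.

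Dividing the 6 libraries into 3 and 3 gives 10 splits, too few for a share under 0.05. By edgeR all 10 gave as many genes as the real split, 0. By DESeq2 only the real split (1 of 10) reached 64 genes, and the highest other gave 17. For gene lists 6 of 10 reached the real 15, and the highest other gave 24. By fry for either direction 1 of 10, the real split, gave a list (1), and the highest other gave 0. Among called lists, the real split gave the smallest camera p for the reactive astrocyte, endothelial and infiltrate lists. It also did so for the mitochondrially encoded and other Wnt ligand lists, which were not called. Chance alone gives a list this rank in 1 of 10 splits, so the rank does not set these lists apart. In every other called list another split gave a camera p as small. With the real split counted, 3 of 10 did for immediate early genes, 2 for the meningeal list, 5 for interferon-stimulated and 10 for ribosomal genes. The lowest camera p in another split was 5.73e-13 for immediate early genes (real 7.44e-07) and 2.31e-13 for the meningeal list (real 3.74e-06).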
